A study of Homo sapiens with 3 samples.

How the data were processed

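The series holds 3 RNA sequencing libraries of PC-3 cells, 2 labelled KMT2D shRNA and 1 labelled control shRNA, each collected 7 days after lentiviral infection. Per the labels' protocols, polyadenylated RNA was selected with oligo(dT) beads, fragmented, reverse transcribed with random primers, amplified and sequenced on a BGISEQ-500. The protocol names no step that marks strand, so overlapping and antisense genes could not be told apart. Per the submitters' processing notes, hg19, HISAT and Bowtie2 were used. Their roles and versions are not given in the sources used here, nor is the tool that counted reads.

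The authors deposited 1 table per library with a gene's Entrez identifier, RefSeq transcripts, length, expected count and FPKM, per the file headers. The expected counts that the authors deposited are estimated reads per gene without normalization, and about 68% of them were whole numbers (67.8% to 68.0% by library, tested as exact integers). FPKM, the deposited second measure, is scaled by transcript length and by library total, per the file headers, and was checked against the counts and lengths. The length in bases, also per the file headers, can differ between libraries for genes with several transcripts, and the mean over libraries was used. A gene left out of a library's table was taken as 0 here. Listed genes had expected counts above 0, apart from 1 gene at 0 in KMT2D shRNA library 2.

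The tables were joined on the Entrez identifier, giving 18331 identifiers in any library and 15771 in all 3. Names came from a RefSeq gene table of the assembly GRCh38.p14, used for names only: 18214 identifiers matched directly, 28 through a transcript, and 89 did not match (99.5% matched). Transcript GC content came from GENCODE transcript sequences and was had for 98.8% of tested genes.

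Expected counts were rounded to whole numbers. Totals were 5157550, 5123817 and 5559504 for KMT2D shRNA library 1, library 2 and the control, and the 10 most abundant genes held 3.7%, 4.2% and 4.4% of them. A count of 3, taken as the floor, was 0.573, 0.591 and 0.545 CPM. Intervals and floors cover counting error only, because reads amplified without molecular identifiers are not independent molecules. Library 1 and library 2 differed by a chi-square of 5.46 per gene, above sampling noise, and were counted as separate samples. This does not show that they came from separate cultures, since the spread may be technical. Each differed from the control by 42.5 and 41.7 per gene.

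The main test was edgeR 4.0.16 in R 4.3.3, with its default filter on low counts by group, TMM scaling and the quasi-likelihood F test on group alone, Benjamini-Hochberg adjusted, at a threshold of 0.05. It has 1 residual degree of freedom. The common dispersion was 0.0119, a biological coefficient of variation of 10.9%, and the prior degrees of freedom were 45.7. CPM values are TMM-scaled, and SE values are derived from the F statistic. Fold changes per library used log2 CPM with a prior count of 2. On simulated data for this comparison, with 200 changed genes among 13831 and no length trend, the test recovered 10.6% of 1.5-fold, 70.1% of 2-fold and 98.5% of 4-fold changes and called 7 unchanged genes. With a simulated length trend it called 928 unchanged genes of 13814 tested, and 4 once the trend was removed. That trend was the one fitted to these data and was removed by the same kind of fit, so the removal was bound to work. The simulated control was drawn at the fitted dispersion, so these counts do not cover a control library with a state of its own.

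Before the data were examined, 37 gene lists with 700 written members were fixed, of which 684 entries were matched to distinct genes. The 30 lists with at least 5 tested genes were tested with camera in limma 3.58.1 on log2 CPM with a preset correlation of 0.01, Benjamini-Hochberg adjusted over the 30 lists, and again with an estimated correlation, which leaves 1 degree of freedom. No list passed with the estimated correlation, so a call lost there does not tell a strong list from a weak one. Random lists numbered 10000 per list, matched on mean expression in 20 bins, and on the interferon response list both labelled libraries fell at percentile 0 among them. Named genes were also fixed before the data were examined: KMT2D, LIFR and KLF4; the 12 genes each way with the largest change in the less changed of the labelled libraries, among genes past the threshold with a mean of 5 CPM or more; on each list, up to 4 members by the same ranking and members past the threshold; and the 4 genes each way that differ most between the labelled libraries. Chance values for libraries that share a control were taken from 100 simulated draws. These used the fitted dispersion, which rests on the spread between the labelled libraries because the control has no replicate.

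Alternatives fixed before the data were examined were DESeq2 size factors or library totals for scaling, other filters and prior counts, DESeq2 1.42.0, limma-voom, edgeR's robust option, limma on log2(FPKM + 1) or log2(FPKM + 0.1), and leaving out each labelled library. Chosen after seeing the data were fits with each library's loess trend with log length, GC content or both removed (span 0.4), and a fit without genes that share reads. No batch or date was given in the labels. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.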

Results

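Messenger RNA was sequenced from PC-3, an established human prostate cancer cell line, 7 days after infection with lentivirus that expressed short hairpin RNA (shRNA). The series design text calls the profiles retinal while it too names PC-3 cells, and the sample labels were followed. The 3 libraries formed 2 groups. The KMT2D shRNA group held 2 libraries, numbered 1 and 2 in the labels, and the control shRNA group held 1. The labels do not say whether the libraries came from separate cultures or whether the numbers stand for different hairpins. The p-values of edgeR thus measure only the spread between these libraries, pooled across genes, which may be technical. Those of camera at the preset correlation compare the genes of a list with other genes, and genes are not independent replicates. Library totals were 5157550 estimated counts for KMT2D shRNA library 1, 5123817 for library 2 and 5559504 for the control. At 10 counts or more, 13484, 13412 and 13580 genes were covered in these libraries. The control had no replicate, so no SD is given for it, and the test assumed that it varied like the libraries labelled KMT2D shRNA. The deposited processing used the genome build hg19, and no coordinates are given because the annotation used here for gene names is of another build.

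The level of KMT2D, the targeted gene, was read first in every library. KMT2D encodes a histone methyltransferase of enhancers, and its RNA was not lower in either library labelled KMT2D shRNA. KMT2D (Entrez gene 8085) had 107 CPM (counts scaled to a common library total) in library 1 and 138 CPM in library 2, against 100.1 CPM in the control library. These levels rested on 562, 699 and 551 counts, and the deposited FPKM values of KMT2D were 5.53, 6.93 and 5.02. The ratio of KMT2D to the control was 1.07 in library 1 (95% interval 0.953 to 1.21) and 1.38 in library 2 (1.23 to 1.54). These intervals cover counting error only. KMT2D averaged 123 ± 21.4 CPM (SD, n = 2) in the group, a log2 fold change of 0.29 (SE 0.18) that missed the threshold of edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p = 0.227). As fitted, the target was thus not shown to be lower. Every direction below is given for the libraries labelled KMT2D shRNA, not for a loss of KMT2D. With a trend of fold change with transcript length removed, the log2 fold change of KMT2D turned to -0.66 (edgeR adjusted p = 0.00881), and with a GC trend removed as well it was -0.54 (edgeR adjusted p = 0.0874); over all alternatives the adjusted p of KMT2D ran from 0.00881 to 0.58. The transcript of KMT2D is 19432 bases long. Among the 200 tested genes nearest to it in length its fold change stood at percentile 17.5 in library 1 and 30.5 in library 2. Those genes had a median log2 fold change of 0.84 in library 1 and 0.796 in library 2. Among the 50 nearest, of 14461 bases or longer, KMT2D stood at percentiles 10 and 14.

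LIFR, a receptor subunit for leukemia inhibitory factor, and KLF4, a transcription factor, were named before the data were examined. LIFR (Entrez gene 3977) rose from 17.4 CPM in the control to 40.2 ± 4.71 CPM (SD, n = 2) in the libraries labelled KMT2D shRNA, a log2 fold change of 1.20 (SE 0.23, edgeR adjusted p = 4.81e-05). For LIFR the log2 fold change with the length trend removed was 0.56 and no longer passed (edgeR adjusted p = 0.0824). KLF4 (Entrez gene 9314) fell from 80.3 CPM to 32.8 ± 4.96 CPM (SD, n = 2), a log2 fold change of -1.29 (SE 0.18, edgeR adjusted p = 2.9e-07). For KLF4 it was then -1.28 (edgeR adjusted p = 3.31e-06).

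**Figure D1:**
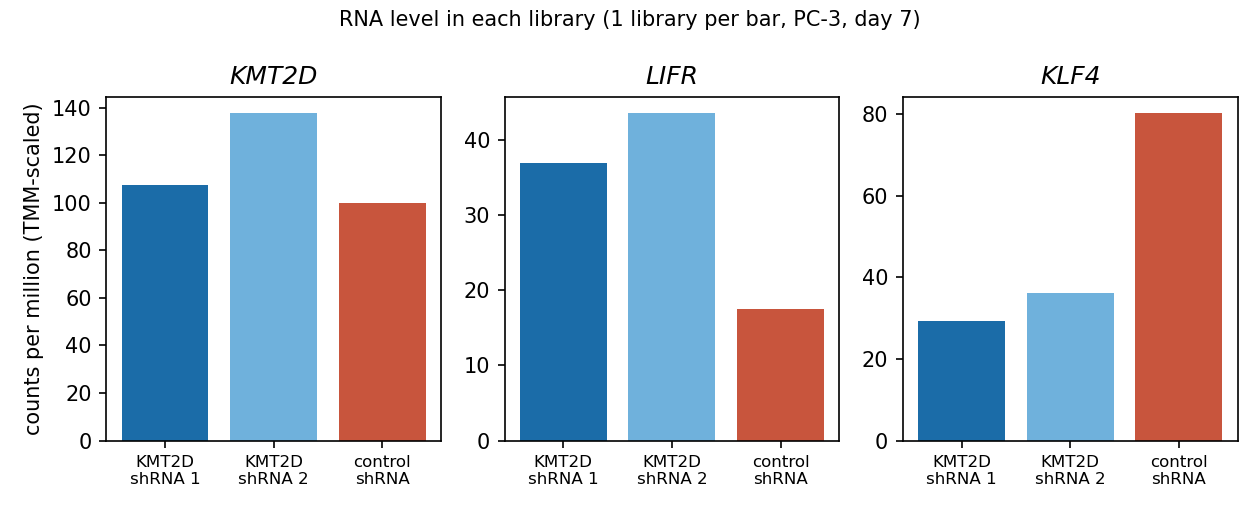
Bars give the TMM-scaled CPM of KMT2D, LIFR and KLF4 in each of the 3 libraries, 1 library per bar, with no error bar because each bar is 1 library. KMT2D stood at 107, 138 and 100.1 CPM in KMT2D shRNA library 1, library 2 and the control, so neither labelled library lay below the control.

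The main comparison asked which genes differed between PC-3 cells given KMT2D shRNA and cells given control shRNA. Genes induced by interferon fell most: all 24 tested genes of the interferon response list were lower in the libraries labelled KMT2D shRNA, with a median log2 fold change of -4.39. Genes of the unfolded protein and integrated stress response fell as well (12 of 20 tested, median -0.87). Genes of the G2/M phase of the cell cycle rose (17 of 22, median 0.61), and so did integrin and extracellular matrix genes (17 of 24, median 0.92). None of these 4 list calls held with an estimated correlation (camera adjusted p = 0.535 for each). That setting has 1 degree of freedom, and no list passed in it. With the length trend removed the integrin and matrix median was 0.42 with 9 genes that rose. Across the transcriptome 4352 of 14016 tested genes passed edgeR's quasi-likelihood test at an adjusted p under 0.05, of which 2319 rose and 2033 fell. Fold change followed transcript length, with Spearman coefficients across genes of 0.456 in library 1 and 0.46 in library 2 (genes are not independent replicates) against 0.0307 between those libraries. With that trend removed 2572 genes passed, 1257 higher and 1315 lower, and these held 1104 of the genes that rose and 984 of those that fell. DESeq2 called 1202 genes, edgeR without a filter on low counts 1897, and limma on FPKM 0 in each of 3 settings, where 4168 to 4568 genes had an unadjusted p under 0.05 against 5711 with edgeR.

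**Figure D2:**
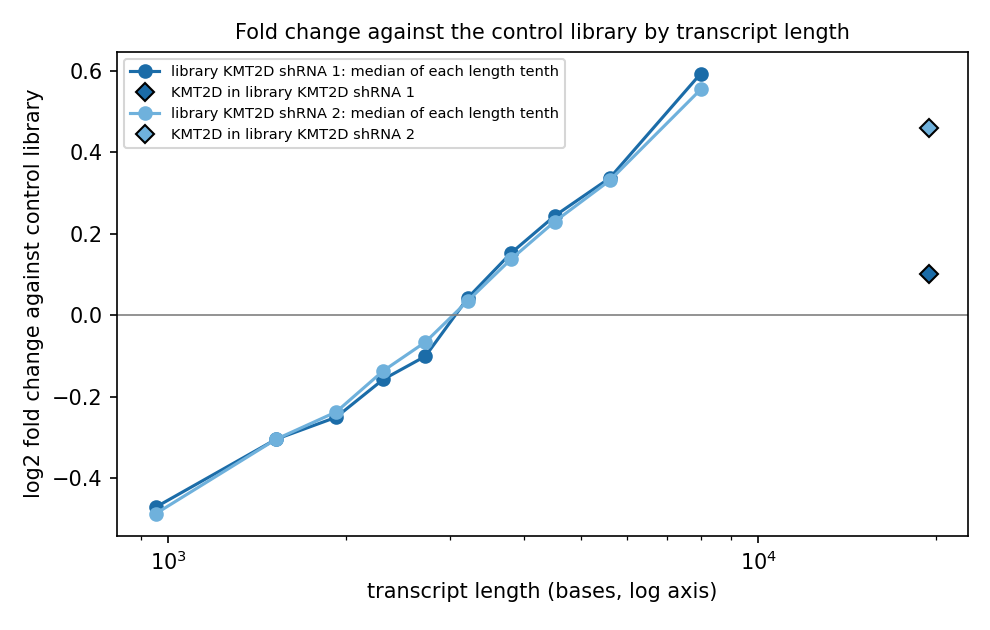
Circles give the median log2 fold change against the control library (vertical axis) of the genes in each of 10 equal classes of transcript length (horizontal axis, bases, log scale) for KMT2D shRNA libraries 1 and 2, and diamonds give KMT2D itself. The medians climbed from -0.47 and -0.49 in the shortest class to 0.59 and 0.56 in the longest, and KMT2D lay at 0.10 and 0.46.

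Interferon-stimulated genes stood at far higher levels in the control library than in either library labelled KMT2D shRNA. BST2, which tethers budding virus particles to the cell surface, was at 320 CPM in the control and at 1.65 ± 0.447 CPM (SD, n = 2) in the labelled libraries, a log2 fold change of -7.58 (SE 0.25, edgeR adjusted p = 3.31e-29). ISG15, a ubiquitin-like protein, fell from 3076 CPM to 99.0 ± 6.78 CPM (SD, n = 2), a log2 fold change of -4.96 (SE 0.16, edgeR adjusted p = 3.09e-29). The weakest fall on the list was that of IRF9, part of the transcription factor complex that drives these genes, with a log2 fold change of -1.68 (SE 0.18, edgeR adjusted p = 2e-10). The antiviral effectors OASL, RSAD2, IFITM1, IFI6, MX1, MX2, IFIT1 and IFI27 lay between, with log2 fold changes from -6.51 for OASL to -4.69 for MX1. All 24 members fell over all genes tested and also when adjusted over the list alone. The list stood apart by camera with a preset correlation (adjusted p = 5.21e-44), a call that did not hold with an estimated correlation (adjusted p = 0.535). No list passed with the estimated correlation, which leaves 1 degree of freedom, so that value cannot decide for or against the list. With the length trend removed all 24 still fell, with a median log2 fold change of -4.18. Of the leukocyte genes, CD68 fell from 150 to 50.8 ± 7.00 CPM (SD, n = 2, edgeR adjusted p = 6e-10) and LYZ from 32.9 to 21.1 ± 2.01 CPM (SD, n = 2, edgeR adjusted p = 0.0189, or 0.286 with the length trend removed).

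**Figure D3:**
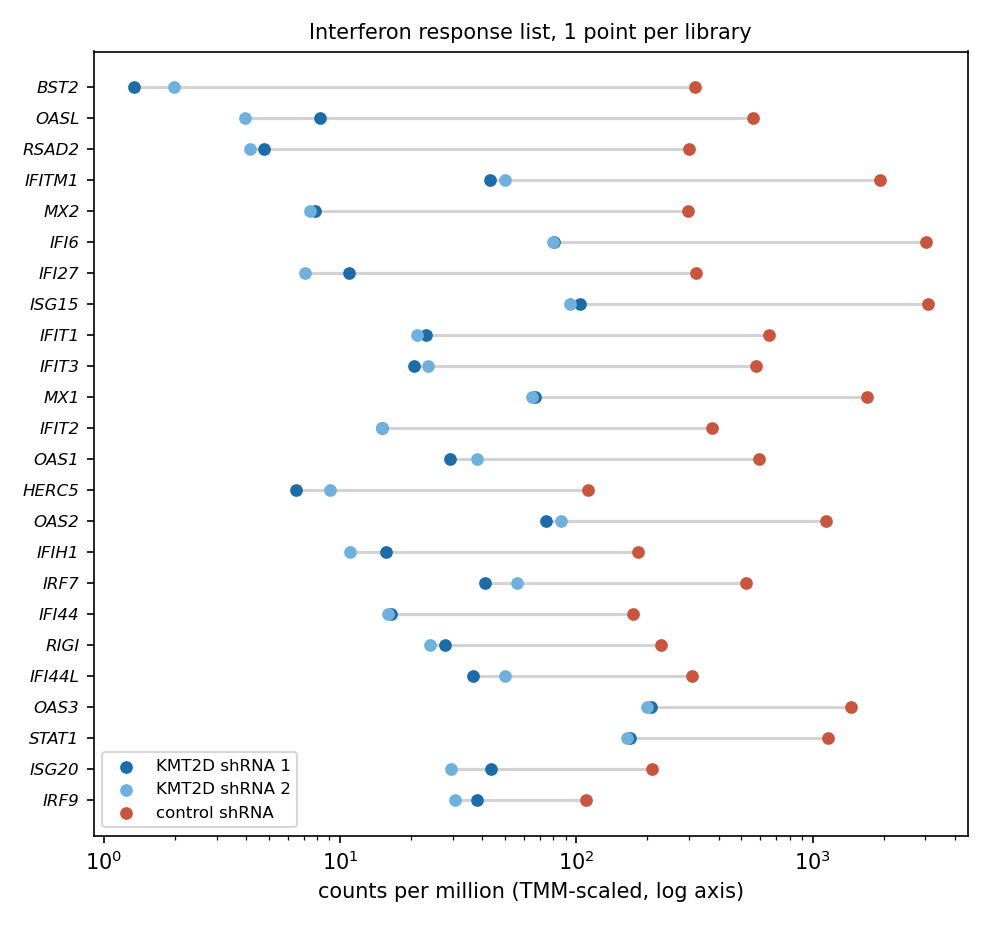
Each row is a gene of the interferon response list, and the 3 points give its TMM-scaled CPM (log axis) in KMT2D shRNA library 1, library 2 and the control library. In all 24 rows both labelled libraries lie to the left of the control, as for BST2 at 1.34 and 1.97 against 320 CPM.

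Inflammatory and stress genes were also lower in the libraries labelled KMT2D shRNA. On the NF-kB cytokine list 9 of 17 tested genes fell and 1 rose, or 10 and 1 when adjusted over the list alone, with a median log2 fold change of -0.55 (camera adjusted p = 0.00174, or adjusted p = 0.535 with an estimated correlation). IL6, an inflammatory cytokine, fell from 49.6 to 4.78 ± 2.16 CPM (SD, n = 2), a log2 fold change of -3.37 (SE 0.25, edgeR adjusted p = 3.6e-15), and the neutrophil chemokine CXCL8 fell by 1.39 on the log2 scale (SE 0.17, edgeR adjusted p = 8.25e-09). CXCL5, another neutrophil chemokine, was the member that rose (log2 fold change 0.92, SE 0.18, edgeR adjusted p = 0.00012). On the unfolded protein and integrated stress response list 12 of 20 fell and 1 rose, or 13 and 1 when adjusted over the list alone (camera adjusted p = 3.26e-06, or adjusted p = 0.535 with an estimated correlation). Members that fell included ATF4, the central transcription factor of the integrated stress response, at -1.10, its partner DDIT3 at -1.73, the pseudokinase TRIB3 at -1.77 and the asparagine synthetase ASNS at -1.73. ERN1, a sensor of misfolded protein, rose by 0.76 on the log2 scale (SE 0.24, edgeR adjusted p = 0.0121), a call lost with the length trend removed (0.59, edgeR adjusted p = 0.086). Among the 17 tested immediate early genes 7 fell and 0 rose, over all genes and when adjusted over the list alone (median -0.37, camera adjusted p = 0.00772, or adjusted p = 0.535 with an estimated correlation). ATF3 fell by 1.88 on the log2 scale and JUNB by 1.54. With the length trend removed these lists stayed lower, with median log2 fold changes of -0.43 for NF-kB cytokines (camera adjusted p = 0.00826), -0.69 for the stress response (2e-06) and -0.28 for immediate early genes (0.0124), though with an estimated correlation the adjusted p was 0.634 for each. The immediate early call was also lost without a filter on low counts (camera adjusted p = 0.269), on FPKM (0.0578 to 0.391), and with the GC trend or both trends removed (0.0562 and 0.0764). The median of immediate early genes was -0.235 in library 1 alone and -0.39 in library 2 alone.

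On the G2/M list 17 of 22 genes rose and 0 fell, or 18 and 0 when adjusted over the list alone (camera adjusted p = 2.58e-07, or adjusted p = 0.535 with an estimated correlation). TOP2A, the topoisomerase of chromosome segregation, rose from 57.0 to 203 ± 10.3 CPM (SD, n = 2), a log2 fold change of 1.83 (SE 0.19, edgeR adjusted p = 1.26e-10). The mitotic kinesin KIF20A rose by 1.64 on the log2 scale and the proliferation marker MKI67 by 1.45, or by 0.73 with the length trend removed. The list stayed higher with the length trend removed (16 genes rose, median 0.71, camera adjusted p = 1.19e-10, or adjusted p = 0.634 with an estimated correlation). G1/S genes did not pass as a list (6 of 22 rose and 2 fell, with the same counts when adjusted over the list alone; median 0.17, camera adjusted p = 0.127, or adjusted p = 0.675 with an estimated correlation). The G1/S median was 0.24 in library 1 alone and 0.07 in library 2 alone. With the length trend removed the G1/S list did pass (median 0.25, camera adjusted p = 0.0474), but not with an estimated correlation (adjusted p = 0.78). MCM6, a subunit of the replicative helicase, rose by 1.10 (SE 0.20, edgeR adjusted p = 1.93e-05), whereas the G1 cyclin gene CCND1 fell by 0.53 on the log2 scale (SE 0.15, edgeR adjusted p = 0.0074). Of 11 tested replication-dependent histone genes 8 fell and 0 rose, or 9 and 0 when adjusted over the list alone (median -1.15, camera adjusted p = 5.04e-05, or adjusted p = 0.535 with an estimated correlation). H1-2, a linker histone, fell by 1.67 on the log2 scale, or by 1.05 with both trends removed. RNA was selected with oligo(dT) beads, so the counts do not measure histone RNA without a poly(A) tail. These histone genes are short (median length 546 bases), and with the length trend removed the median was -0.64, 4 fell, and the list still passed (camera adjusted p = 0.0102, or adjusted p = 0.634 with an estimated correlation).

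Cell cycle inhibitor and p53 target genes fell (8 of 18 tested, with 2 that rose, the same counts when adjusted over the list alone; median -0.39, camera adjusted p = 0.0147, or adjusted p = 0.535 with an estimated correlation). The activity of p53 itself was not measured, so this fall does not show that it was lower. CDKN1A, the cyclin-dependent kinase inhibitor p21, fell from 90.5 to 37.7 ± 9.06 CPM (SD, n = 2), a log2 fold change of -1.26 (SE 0.19, edgeR adjusted p = 6.32e-07). SESN2, which fell by 1.55 on the log2 scale, is on the stress response list as well, so these lists are not fully separate. The members that rose were RRM2B, a ribonucleotide reductase subunit, by 0.71 and the RNA-binding protein gene ZMAT3 by 0.81 on the log2 scale. Both calls were lost with the length trend removed (0.44, edgeR adjusted p = 0.0895, and 0.21, edgeR adjusted p = 0.583). Of 21 apoptosis regulators 6 fell and 0 rose by either adjustment, over all genes or adjusted over the list alone (median -0.29, camera adjusted p = 0.0147, or adjusted p = 0.535 with an estimated correlation). Those 6 included genes of opposite action: the pro-apoptotic PMAIP1 fell by 2.29, BAD by 0.94 and BMF by 0.81, and the anti-apoptotic BIRC3 fell by 1.14 and MCL1 by 0.77 on the log2 scale. BAD was at -0.50 with the length trend removed. With both trends removed the calls of BAD (-0.28, edgeR adjusted p = 0.237) and BMF (-0.94, edgeR adjusted p = 0.118) were lost. Both lists passed with the length trend removed (median -0.16, camera adjusted p = 0.0312 for p53 targets and median -0.31, 0.0081 for apoptosis regulators, or adjusted p = 0.634 for each with an estimated correlation). Neither passed without a filter on low counts (camera adjusted p = 0.0757 and 0.0675). The p53 target call was lost as well with the length and GC trends removed (median -0.09, camera adjusted p = 0.0868) and on unfiltered FPKM (0.0666).

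Adhesion and matrix genes rose in the libraries labelled KMT2D shRNA. On the integrin and extracellular matrix list 17 of 24 genes rose and 2 fell, over all genes and when adjusted over the list alone (camera adjusted p = 2.58e-07, or adjusted p = 0.535 with an estimated correlation). ITGA1, a collagen-binding integrin subunit, rose from 25.8 to 120 ± 2.63 CPM (SD, n = 2), a log2 fold change of 2.21 (SE 0.20, edgeR adjusted p = 2.8e-12). ITGB1, the common beta subunit, rose by 1.21 (SE 0.17, edgeR adjusted p = 1.43e-07), and the basement membrane collagen gene COL4A1 rose by 1.54 (SE 0.20, edgeR adjusted p = 2.45e-08). ITGA3 and ITGA5 fell by 0.66 and 0.67 on the log2 scale. The list's transcripts are long (median length 5843 bases), and with the length trend removed its median was 0.42, with 9 genes that rose and 2 that fell (camera adjusted p = 0.00126, or adjusted p = 0.634 with an estimated correlation). The mesenchymal list did not pass (6 of 19 rose and 1 fell, or 7 and 3 when adjusted over the list alone; median 0.38, or 0.41 in library 1 alone and 0.23 in library 2 alone; camera adjusted p = 0.106) except at a mean of 5 CPM or more (camera adjusted p = 0.0153), although FN1, which encodes fibronectin, rose by 2.22 (SE 0.17, edgeR adjusted p = 1.38e-14) and CDH2, or N-cadherin, by 1.18 (SE 0.19, edgeR adjusted p = 2.86e-06).

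Epithelial genes fell (6 of 18 tested and 0 rose, the same counts when adjusted over the list alone; median -0.26, camera adjusted p = 0.0284, or adjusted p = 0.535 with an estimated correlation). The keratin genes KRT7, KRT18, KRT19 and KRT8 fell by 1.60, 0.88, 0.75 and 0.67 on the log2 scale, and the tight junction gene CLDN4 fell by 0.92. The calls of KRT19 and KRT8 were lost with the length trend removed (edgeR adjusted p = 0.0505 and 0.0634). Those of KRT18 (-0.44, edgeR adjusted p = 0.0753) and CLDN4 (-0.54, edgeR adjusted p = 0.122) were lost with both trends removed. The epithelial list passed with the length trend removed (median -0.35, camera adjusted p = 0.0124, or adjusted p = 0.634 with an estimated correlation), but not without a filter on low counts (camera adjusted p = 0.263) or on the FPKM scale (camera adjusted p = 0.108 to 0.322). Invasion proteases did not move as a list: 4 of 17 rose and 4 fell, or 4 and 5 when adjusted over the list alone (median -0.07, or -0.21 in library 1 alone and -0.11 in library 2 alone; camera adjusted p = 0.135), and 1 rose and 4 fell with the length trend removed. TIMP1, an inhibitor of metalloproteinases, fell from 1033 to 293 ± 41.6 CPM (SD, n = 2), a log2 fold change of -1.82 (SE 0.16, edgeR adjusted p = 5.28e-13).

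Hypoxia and glycolysis genes fell (11 of 23 tested and 0 rose, or 12 and 1 when adjusted over the list alone; median -0.39, camera adjusted p = 0.00121, or adjusted p = 0.535 with an estimated correlation). PFKFB4, a regulator of glycolytic flux, fell by 0.92 and VEGFA, an angiogenic factor, by 0.63 on the log2 scale. The list remained past the threshold with the length trend removed (median -0.24, 6 fell, camera adjusted p = 0.00803), but not with an estimated correlation (adjusted p = 0.634). Fatty acid synthesis genes rose (6 of 11 and 0 fell, or 7 and 0 when adjusted over the list alone; median 0.51, camera adjusted p = 0.00343, or adjusted p = 0.535 with an estimated correlation), led by ACACA, the acetyl-CoA carboxylase, at 1.49 (SE 0.19, edgeR adjusted p = 3.19e-08), or 0.85 with the length trend removed. That call was lost with the length trend removed (median 0.17, 3 rose, camera adjusted p = 0.133). Cholesterol synthesis genes did not pass (2 of 19 rose and 2 fell, or 1 and 2 when adjusted over the list alone; camera adjusted p = 0.954), and 0 rose and 1 fell with the length trend removed.

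Cytosolic ribosomal protein genes and oxidative phosphorylation genes, which have short transcripts, fell. Of 30 ribosomal protein genes 19 fell and 0 rose, or 20 and 0 when adjusted over the list alone (median -0.45, camera adjusted p = 1.17e-06, or adjusted p = 0.535 with an estimated correlation), as with RPLP2, which fell by 0.93 on the log2 scale. Of 24 oxidative phosphorylation genes 10 fell and 2 rose, also when adjusted over the list alone (median -0.30, camera adjusted p = 0.0122, or adjusted p = 0.675 with an estimated correlation), as with COX5B, which fell by 0.97. With the length trend removed both directions turned and neither list passed, at a median of 0.08 for ribosomal proteins (camera adjusted p = 0.766) and 0.16 for oxidative phosphorylation (camera adjusted p = 0.435). Of ribosomal proteins 1 then rose and 1 fell, of oxidative phosphorylation genes 2 rose and 0 fell, and RPLP2 (-0.33, edgeR adjusted p = 0.17) and COX5B (-0.37, edgeR adjusted p = 0.127) lost their calls.

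Lists of long regulatory genes rose, and none of their calls held once the length trend was removed. On the epigenetic regulator list 15 of 26 rose and 0 fell, or 16 and 0 when adjusted over the list alone (median 0.51, camera adjusted p = 6.29e-05, or adjusted p = 0.535 with an estimated correlation), led by the acetyltransferase EP300 at 1.20 (SE 0.19, edgeR adjusted p = 1.85e-06). On the list of KMT2 methyltransferases and their COMPASS partners 8 of 17 rose and 0 fell, the same when adjusted over the list alone (median 0.29, camera adjusted p = 0.00534, or adjusted p = 0.55 with an estimated correlation), and KMT2A rose by 1.32 and KMT2C by 1.11. On the PI3K-AKT list 10 of 26 rose and 0 fell, or 12 and 1 when adjusted over the list alone (median 0.47, camera adjusted p = 0.00211, or adjusted p = 0.55 with an estimated correlation), with the kinase MTOR at 1.14 and the insulin receptor substrate IRS1 at 1.04. DNA repair genes rose (9 of 24 and 0 fell, or 11 and 0 when adjusted over the list alone; median 0.30, camera adjusted p = 0.00422, or adjusted p = 0.535 with an estimated correlation), with XRCC2 at 1.17. Notch, Wnt and Hedgehog genes rose (6 of 18 and 0 fell, or 7 and 0 when adjusted over the list alone; median 0.48, camera adjusted p = 0.012, or adjusted p = 0.535 with an estimated correlation), with NOTCH3 at 1.67. Once the length trend was removed, 1 epigenetic regulator rose and 0 fell (camera adjusted p = 0.223), 0 COMPASS genes rose and 1 fell (0.497), 5 PI3K-AKT genes rose and 1 fell (0.539), 3 DNA repair genes rose and 0 fell (0.0821), and 2 Notch, Wnt and Hedgehog genes rose and 0 fell (0.105). The COMPASS gene that then fell was KMT2D, the target itself (-0.66, edgeR adjusted p = 0.00881). KMT2A then stood at 0.45 (edgeR adjusted p = 0.0803), KMT2C at 0.23 (edgeR adjusted p = 0.459) and IRS1 at 0.46 (edgeR adjusted p = 0.0652). EP300 stood at 0.63 and MTOR at 0.56. With both trends removed the calls of EP300 (edgeR adjusted p = 0.0597), MTOR (0.104) and NOTCH3 (0.0567) were lost. The COMPASS median was 0.26 in library 1 alone and 0.46 in library 2 alone. The median of the PI3K-AKT list was then -0.03 although the test still pointed up.

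**Figure D4:**
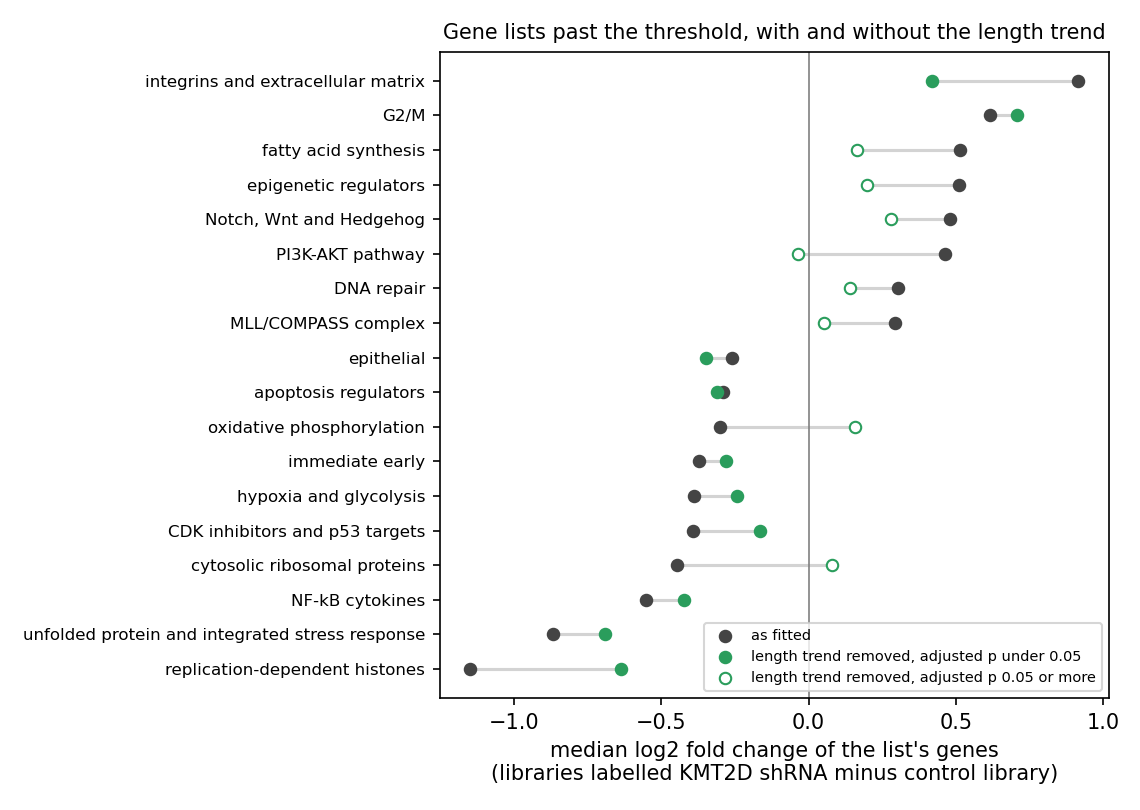
Points give the median log2 fold change (horizontal axis, libraries labelled KMT2D shRNA minus control) of the gene lists past the threshold, interferon response left out for scale, as fitted (dark) and with the length trend removed (green, open where the adjusted p was 0.05 or more). Ribosomal proteins moved from -0.45 to 0.08 and integrins and matrix from 0.92 to 0.42, whereas G2/M stood at 0.61 and 0.71.

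The remaining lists did not pass as lists. LIF, IL6 and STAT3 pathway genes split, with 4 of 16 higher and 4 lower by the test (also when adjusted over the list alone; camera adjusted p = 0.59): LIFR, JAK1, IL6ST and OSMR rose, and IL6, SOCS1, PIM1 and BCL3 fell. In this list 0 rose and 2 fell, IL6 and PIM1, once the length trend was removed. TGF-beta and BMP genes split likewise, 4 up and 3 down of 20 (also when adjusted over the list alone; camera adjusted p = 0.602), with GDF15, a stress-induced cytokine, at -2.16 (SE 0.18, edgeR adjusted p = 7.78e-14). YAP-TEAD targets gave 5 up and 1 down of 13, or 6 and 1 when adjusted over the list alone (camera adjusted p = 0.119), and 2 up and 2 down with the length trend removed. Basal and stem-like genes gave 3 up and 1 down of 11 (also when adjusted over the list alone; camera adjusted p = 0.59), and luminal genes 2 up and 0 down of 9 (also when adjusted over the list alone; camera adjusted p = 0.267). Antioxidant genes gave 2 up and 2 down of 19 (also when adjusted over the list alone; camera adjusted p = 0.602), and ribosome biogenesis genes 1 up and 5 down of 20 (also when adjusted over the list alone; camera adjusted p = 0.307), or 1 and 2 with the length trend removed. Lists for other cell types had too few tested genes for camera. The fibroblast list had 3 tested genes, of which PDGFRA rose. Of 3 tested leukocyte genes CD68 and LYZ fell, of 2 endothelial genes KDR rose, and of 2 neural genes NEFL rose. Of 4 tested retina genes OPN1SW rose and CRX fell (the calls of KDR and OPN1SW were lost with the length and GC trends removed, edgeR adjusted p = 0.126 and 0.0741), and the 2 tested neuroendocrine genes did not pass. None of the 13 mitochondrially encoded genes matched to the reference was listed in these libraries.

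Among genes with a mean of 5 CPM or more, the 12 largest falls in both labelled libraries were BST2, OASL, RSAD2, TRIM22, IFITM1, IFI6, MX2, ISG15, IFI27, IFIT1, MX1 and CMPK2. TRIM22, an interferon-induced ubiquitin ligase, fell by 6.09 on the log2 scale and CMPK2, a mitochondrial nucleotide kinase, fell by 5.01. Of the 12 largest rises, 5 were of genes whose reads overlap those of other genes and are uncertain: SLMO2-ATP5E, ARMCX5-GPRASP2, TMX2-CTNND1, STAG3L1 and SNCAIP-AS3. SLMO2-ATP5E, ARMCX5-GPRASP2 and STAG3L1 had 0 counts in the control and were at least 27.5-fold, 19.3-fold and 13.9-fold higher, taken against a floor of 3 counts in that library. SNCAIP-AS3 lost its call with edgeR's robust option (adjusted p = 0.0919), as did TMX2-CTNND1 (adjusted p = 0.456), which also lost it without a filter on low counts (edgeR adjusted p = 0.0751), with DESeq2 (adjusted p = 0.0771) and with the length and GC trends removed (edgeR adjusted p = 0.0848). The others were ZBED6, HMCN1, PRKAR2A, PCDHA13, EDIL3, POLR2J2 and an Entrez gene, 643314, that the name table did not match. ZBED6, PCDHA13 and POLR2J2 lie within or resemble other genes and are uncertain too. EDIL3, a secreted integrin ligand, rose by 2.48 (SE 0.24, edgeR adjusted p = 9.09e-12), HMCN1, an extracellular matrix protein gene, by 2.61 (SE 0.31, edgeR adjusted p = 5.72e-09; 1.69 with the length trend removed), and PRKAR2A, a regulatory subunit of protein kinase A, by 2.62 (SE 0.26, edgeR adjusted p = 3.35e-11).

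The next comparison asked how far both libraries labelled KMT2D shRNA departed from the control in the same way. BST2, OASL and ISG15 were lower and ITGA1, EDIL3 and TOP2A were higher in each of them. At 2-fold or more, 702 genes were higher and 528 lower in both labelled libraries, and 3 genes moved 2-fold in opposite ways. For unchanged libraries that share the control, simulation gave 43.1 and 19.9 genes, and independent lists of the observed sizes would share 76.1 and 50.5. The simulated libraries held no length trend, whereas both labelled libraries had one against the control. With that trend removed 448 genes were higher and 465 lower in both. The log2 fold changes correlated across genes with Pearson's r of 0.857 (simulated 0.489) and Spearman's rho of 0.851 (simulated 0.462), and the covariance was 0.517 against 0.0637 simulated, a difference of 0.454. With the length trend removed Pearson's r was 0.833. Genes are not independent replicates, so no p is given. With 1 control library the control could not be split. Part of the excess may come from the shared control or from the length trend that the simulation left out.

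Between the libraries labelled KMT2D shRNA the largest differences were at overlapping genes. BMS1P2, SLX1B-SULT1A4, C8orf44-SGK3 and NME1-NME2 were higher in library 1 than in library 2. ARL2-SNX15, SLX1A-SULT1A3, PCDHGC3 and POC1B-GALNT4 were higher in library 2 than in library 1. All but PCDHGC3, a member of the protocadherin gamma cluster, are read-through genes or pseudogenes whose reads can be assigned to more than 1 gene, and PCDHGC3 shares exons within its cluster. PCDHGC3 had 1 count in library 1, 56 in library 2 and 242 in the control. In all, 362 genes differed 2-fold or more between these libraries, against 1941 and 1809 between each of them and the control. Of the 362, only 67 were marked as sharing reads, and 295 genes differed in the fit without such genes. Simulated unchanged libraries gave 270 genes. Their dispersion was fitted to the spread between these same labelled libraries, so that number is not an independent measure of chance. With 1 library on each side the difference between the labelled libraries has no replicate check.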

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

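Fits with a length or GC trend removed, and the fit without genes that share reads, were chosen after seeing the data. The main count of 4352 genes fell to 1897 with no filter on low counts, to 1202 with DESeq2 (3533 genes had no adjusted p), to 2572 with the length trend removed and to 1366 with the length and GC trends removed. It was 0 by limma on FPKM with a pseudocount of 1, with a pseudocount of 0.1 and with no filter, where 4274, 4168 and 4568 genes had an unadjusted p under 0.05 and the smallest adjusted p was 0.0673, 0.112 and 0.171. The prior degrees of freedom of edgeR ranged from 4.93 to 45.8 between settings, and the cause of these moves was not tested. With 1 labelled library left out no residual degree of freedom remains, so the main test could not be fitted. Genes changed 2-fold numbered 1230 in both labelled libraries and 1809 to 1941 in either one alone.

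Pearson's r between the labelled libraries, 0.857, was 0.794 with no filter, 0.851 and 0.898 at a mean of 1 and 5 CPM or more, 0.832 with a prior count of 0.5, and 0.826, 0.723 and 0.817 on FPKM with a pseudocount of 1, of 0.1 and with no filter. It was 0.833 with the length trend removed, 0.832 with both trends removed and 0.876 without genes that share reads. Genes that differed 2-fold between those libraries, 362, numbered 1055 with no filter, 92 at a mean of 5 CPM or more and 646 on FPKM with a pseudocount of 0.1. The low counts that a filter admits or removes thus set much of that number.

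KMT2D stood at a log2 fold change of 0.29, at 0.10 and 0.46 with either labelled library alone, and turned to -0.656 with the length trend removed and to -0.54 with both trends removed. Gene lists past the threshold numbered 19, then 12 with the length trend removed, 10 with both trends removed and 0 with an estimated correlation, where camera has 1 degree of freedom. Ribosomal proteins turned to medians of 0.0788 and 0.0912, and oxidative phosphorylation to 0.158 and 0.107, with the length trend and with both trends removed. The cause was not tested. For single lists, 420 alternative values had a test: 362 kept direction and side of the threshold, 6 turned sign with no call either way, 43 lost the call, 6 lost it and turned, and 3 gained it. For 26 named genes, LIFR, KLF4 and the 12 largest changes each way, 271 of 356 values with a test kept both. The other 85 lost the call, 78 of these on FPKM, where no gene passed. The largest changes were picked from the main fit, so their calls were likely to hold in fits of the same libraries. The remaining named genes are not in these counts. Over all genes, 47.6% of the rises and 48.4% of the falls kept their call with the length trend removed. With both trends removed 25.3% and 28.3% kept it. Values with a library left out had no test, and 58 of 60 for lists and 52 of 52 for those 26 genes kept direction. No paired analysis was possible because the control group has 1 library and its label carries no replicate number.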

Other observations

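Groups in this and the next paragraph were chosen after their values were seen. Antigen presentation genes followed the interferon response list: 13 of 14 fell in the libraries labelled KMT2D shRNA by edgeR's test, with a median log2 fold change of -2.41, and 13 fell with the length trend removed. HLA-B, a class I heavy chain, fell from 710 to 86.9 ± 7.73 CPM (SD, n = 2), and B2M, the class I light chain, fell from 2642 to 531 ± 41.3 CPM (SD, n = 2). PSMB9, an immunoproteasome subunit, fell by 4.12 on the log2 scale and NLRC5, the activator of class I genes, by 3.36, whereas the trimming peptidase ERAP1 stood at -0.03 (edgeR adjusted p = 0.921). Reads of interferon genes were few. In the control library IFNB1 had 9 counts, IFNL1 had 11, IFNL3 had 4 and IFNL2 had 1, and each had 0 counts in both labelled libraries. IFNE, the only interferon gene tested, had 21, 27 and 18 counts in library 1, library 2 and the control (log2 fold change 0.51, edgeR adjusted p = 0.463). Of 16 interferon receptor and signalling genes 2 rose and 8 fell, or 0 and 7 with the length trend removed. JAK1 (0.63, edgeR adjusted p = 0.00534) and MAVS (0.70, edgeR adjusted p = 0.00164) were those that rose, IFNAR1 stood at 0.45 (edgeR adjusted p = 0.0517), and STAT2, which carries the interferon signal, fell by 1.86. The 24 genes of the interferon response list took 1.92% of all counts in the control and 0.111% and 0.108% in KMT2D shRNA libraries 1 and 2. ISG15 and IFI6 ranked 15 and 16 by count among all genes of the control library and 2531 and 3057 in library 2.

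Genes of aminoacyl-tRNA synthetases and amino acid transport fell alongside ATF4, which is known to drive many of them. Whether ATF4 accounts for their fall was not tested. Of 16 tested, 10 fell and 0 rose, and the counts were 10 and 0 with the length trend removed. CARS1 fell by 1.25, WARS1 by 1.12 and the transporter subunits SLC3A2 and SLC7A5 by 1.43 and 0.97 on the log2 scale, while IARS1 stood at 0.34 (edgeR adjusted p = 0.13) and EPRS1 at 0.33 (edgeR adjusted p = 0.159). COL6A3 and FAT1 were picked from among the largest rises. COL6A3, a collagen VI chain, rose from 174 CPM in the control to 842 and 904 CPM in libraries 1 and 2, a log2 fold change of 2.33 (SE 0.18, edgeR adjusted p = 1.05e-14) that was 1.72 with the trend removed. The protocadherin FAT1 rose by 2.23, or 1.40 with the trend removed.

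In the weighing that follows, the tests of a response of the lone control culture, of the length trend as the whole cause, of too few reads and of exchanged labels were chosen after the results were seen, as was the removal of the length and GC trends. The first pattern is the low interferon response in both libraries labelled KMT2D shRNA. Leukocytes in the control culture are argued against by PTPRC, ITGAM, CD14, CD3E and CSF1R, since the highest of these there was 1.27 CPM. CD68 and LYZ were not among the genes measured for this. At 150 and 32.9 CPM in the control CD68 and LYZ lay above the mark for leukocytes, but that mark was set for the other genes. They fell to 50.8 ± 7.00 and 21.1 ± 2.01 CPM (SD, n = 2), so both were still read in the labelled libraries. The fall of LYZ lost its call with the length trend removed (edgeR adjusted p = 0.286), and that of CD68 held (edgeR adjusted p = 5.25e-07). Their direction goes with leukocytes in the control. PTPRC, the highest of the genes measured for this, was no higher in the control than in libraries 1 and 2 (1.34 and 2.17 CPM). The length trend is argued against too, since the list's median was -4.18 with it removed. A response of the control culture to its own virus or hairpin, unrelated to KMT2D, may account for the pattern as well as an effect of the KMT2D shRNA, and with 1 control library these cannot be told apart.

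The second pattern is the rise of integrin and extracellular matrix genes. Removal of the GC trend left the list's median log2 fold change at 0.963, which argues against GC content. Removal of the length trend brought the median from 0.917 to 0.421, with a camera adjusted p of 0.00126 at the preset correlation. By the criterion set for it, that goes against length as the whole cause. The criterion was chosen after the results were seen, and its p takes genes as the units, so its weight is limited. With an estimated correlation the camera adjusted p was 0.634, but no list passed in that setting, so this value decides neither way. How much of the pattern length may carry stays open, because 0.421 lies between the bounds set for and against it. An effect of the KMT2D shRNA stays open and untested, since 1 control library cannot separate it from that library's own state.

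The third pattern is that KMT2D RNA was not lower in the libraries labelled KMT2D shRNA. Too few reads are argued against, since the lower 95% limit of the ratio to the control was 0.953 at the least. A length trend that hides a lower level may contribute. With that trend removed the log2 fold change of KMT2D was -0.656 (edgeR adjusted p = 0.00881), and with both trends removed it was -0.54 (edgeR adjusted p = 0.0874). The higher percentile of KMT2D among the 200 genes nearest in length was 30.5 and the lower was 17.5. Among the 50 nearest (14461 bases or longer) they were 14 and 10, nearer to that explanation. Together these values decide neither way. Exchanged labels stay open with 1 control library, because 1 of the 2 possible exchanges would put KMT2D below the then control in both others, but library 2, which it moves, did not stand apart from library 1 (362 genes differed 2-fold, against 1941 and 1809 from the control), which speaks against it. Loss of KMT2D protein without loss of its RNA was not tested.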
